A study of Drosophila melanogaster with 6 samples.

How the data were processed

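Leg discs of third-instar larvae were dissected from flies kept at 25 °C, with 20 discs per replicate. Strand-specific poly-A libraries were sequenced as 150-base paired-end reads on a NovaSeq 6000, per the labels' protocols. The deposited table holds whole-number counts per gene, not normalized, for 3 WT and 3 Double libraries. STAR 2.7.0, HTSeq and DESeq2 and the build dm6 are named, per the submitters' processing notes, with no role or order given here. The strand setting of the counting, the annotation release and any filter are not given in the sources used here. If counting ignored the strand, reads of overlapping genes on opposite strands would be mixed, and reads shared by near-identical copies may have been dropped or assigned to 1 of them.

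The table lists 17612 genes by FlyBase identifier, of which 17540 matched a symbol and position in the Ensembl annotation of BDGP 6.54 (release 115), which shares its coordinates with dm6. The other 72 kept their identifiers. No row was a summary of unassigned reads, and 4525 genes had no count in any library. The total counts ranged from 8818943 to 13605668, so that 1 count equals 0.113 to 0.0735 CPM. A gene at 0 in all libraries of a group was given a floor of 3 counts over the group, and such floors cover counting error only.

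Libraries were grouped by their titles. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 9.49 to 38.8 over the 6 pairs within groups), so each was kept as 1 sample. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersions and group as the only term. The filter filterByExpr by group left 8802 genes to test. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 20.4%. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are scaled with the TMM factors, and means are given with the SD over 3 libraries. Positions were tested with Fisher's exact test and with 10000 random draws of as many tested genes.

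The 29 gene lists, with 620 names, were fixed from textbook knowledge before the data were examined, as were the main test, dac as the candidate target and the rule for named genes. Of the names, 608 distinct genes were matched, and 7 spellings were brought to the annotation's own after the data were seen. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, for the 28 lists with at least 5 tested members. The named genes are dac and the 10 annotated genes on each side, and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with an average log2 CPM of at least 1 and groups that do not overlap. To these are added up to 4 members per list past the threshold, and the 2 members with the smallest p of each of the first 5 lists that have none, as values only. Genes named outside this rule were chosen after their values were seen.

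The test was checked on data simulated from the real means and library sizes for Double against WT, with 200 of 8802 genes changed in each of 10 runs. It called 80.3% of 4-fold falls and 85.8% of 4-fold rises, 61.8% and 72.7% of 2-fold changes, and 39.7% and 43.6% of 1.5-fold changes. Of its calls 8.76% were false, above the nominal 5%, and no called change had the wrong sign. Each gene was simulated independently, so variation shared by many genes, such as that from carried-over tissue, was not part of this check.

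The alternatives were RLE factors, library totals with no factors, no count filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p under 0.01, a test against a 1.5-fold change, windows of 500 and 2000 kb, and each library left out in turn. Covariates for fat body, salivary gland, and neuron and glia markers were added after seeing the data. Correlations and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.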

Results

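Poly-A RNA was sequenced from third-instar larval leg discs of Drosophila melanogaster, the epithelial sacs that give rise to the adult legs. The labels give 2 groups, wild type (WT) and Double, with 3 libraries in each and 20 discs per library. The series describes its second genotype as discs that carry a PRE deletion, a PRE being a Polycomb response element, a DNA element that recruits Polycomb group repressor proteins. The labels name neither the deleted elements nor their locus. The total count per library was 13605668, 8818943 and 10941615 in WT replicates 1, 2 and 3, and 11772621, 11103471 and 10025174 in Double replicates 1, 2 and 3. No label says whether the replicates came from separate crosses or days, so the p-values measure only the spread between these libraries, part of which may be technical.

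The comparison of Double with WT asks which genes change their expression when PREs are deleted, and dac was read before any other gene. dac (dachshund, FBgn0005677) encodes a nuclear protein needed for the intermediate segments of the leg, and it was fixed as the candidate target from background knowledge, since the labels give none. It lies on the minus strand of chromosome arm 2L at 16466512 to 16485998 (dm6). Its expression was 30.7% lower in Double, at 414.4 ± 4.38 CPM (counts scaled to library size; SD, n = 3) against 598.2 ± 16.3 CPM (SD, n = 3) in WT. The log2 fold change of dac was -0.53 (SE 0.06) with an adjusted p of 0.003869 in edgeR's quasi-likelihood test, and all 3 Double libraries lay below all 3 WT libraries. Without Double replicate 3 the log2 fold change of dac was -0.53 and the adjusted p was 0.05363, above the threshold of 0.05. The lowest Double library still read 409.34 CPM.

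CG5888 (FBgn0028523), an annotated protein-coding gene 18 kb from dac, moved the other way. It occupies 16400175 to 16448469 on the minus strand of 2L and rose 3.76-fold, from 47.86 ± 0.71 CPM (SD, n = 3) in WT to 180.0 ± 11.1 CPM (SD, n = 3) in Double. The log2 fold change was 1.91 (SE 0.07; edgeR adjusted p = 5.209e-06). Idgf1, Idgf2 and Idgf3, which encode secreted chitinase-like growth factors, lie on the plus strand on the same side of dac, Idgf1 within and Idgf2 partly within the span of CG5888. Their log2 fold changes were 0.80 (SE 0.42), 0.74 (SE 0.28) and 0.81 (SE 0.47), and none passed the test (edgeR adjusted p = 0.4898, 0.3374 and 0.5573). The libraries were strand-specific, but the strand setting of the counting is not given in the sources used here, so reads of CG5888, Idgf1 and Idgf2 may not be fully separated. In models chosen after seeing the data, with the summed fat body markers described last as a covariate, the log2 fold changes of Idgf1, Idgf2 and Idgf3 were 0.27, 0.41 and 0.29. With the neuron and glia markers as the covariate they were 1.21, 0.96 and 1.31, and there all 3 passed (edgeR adjusted p = 0.0391, 0.02742 and 0.02183). The summed neuron and glia markers were set mainly by nrv2 and CadN, at 206.31 and 165.16 of 495.6 CPM in WT replicate 1. That sum may therefore not measure neural tissue.

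On the other side of dac, Tpr2, which encodes a co-chaperone, stood at 286.7 ± 5.36 CPM in WT and 295.6 ± 16.9 CPM in Double (SD, n = 3 each), a log2 fold change of 0.04 (SE 0.07). Of the 21 genes made up of dac and the 10 annotated genes on each side, 11 had enough counts to be tested, 1 was higher and 1 lower, and the counts adjusted over the list alone were also 1 and 1. The log2 fold changes of the remaining tested neighbours were 0.08 for chif, -0.13 for CG4455, 0.02 for CaBP1, 0.01 for CG5953 and 0.00 for mtgo, with SEs of 0.07, 0.07, 0.12, 0.21 and 0.08 in the same order, and none passed the test. The non-coding gene lncRNA:CR44994, 4.2 kb from dac, had 0 counts in each WT library and 3, 4 and 3 counts in the Double libraries, too few to be tested. Within 1 Mb of dac 2 of 93 tested genes had changed (2.15%), against 129 of 8709 elsewhere (1.48%; one-sided Fisher's exact test, p = 0.4044). With the neuron and glia covariate, chosen after seeing the data, 9 genes within 1 Mb had changed (one-sided Fisher's exact test, p = 0.1189).

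**Figure D1:**
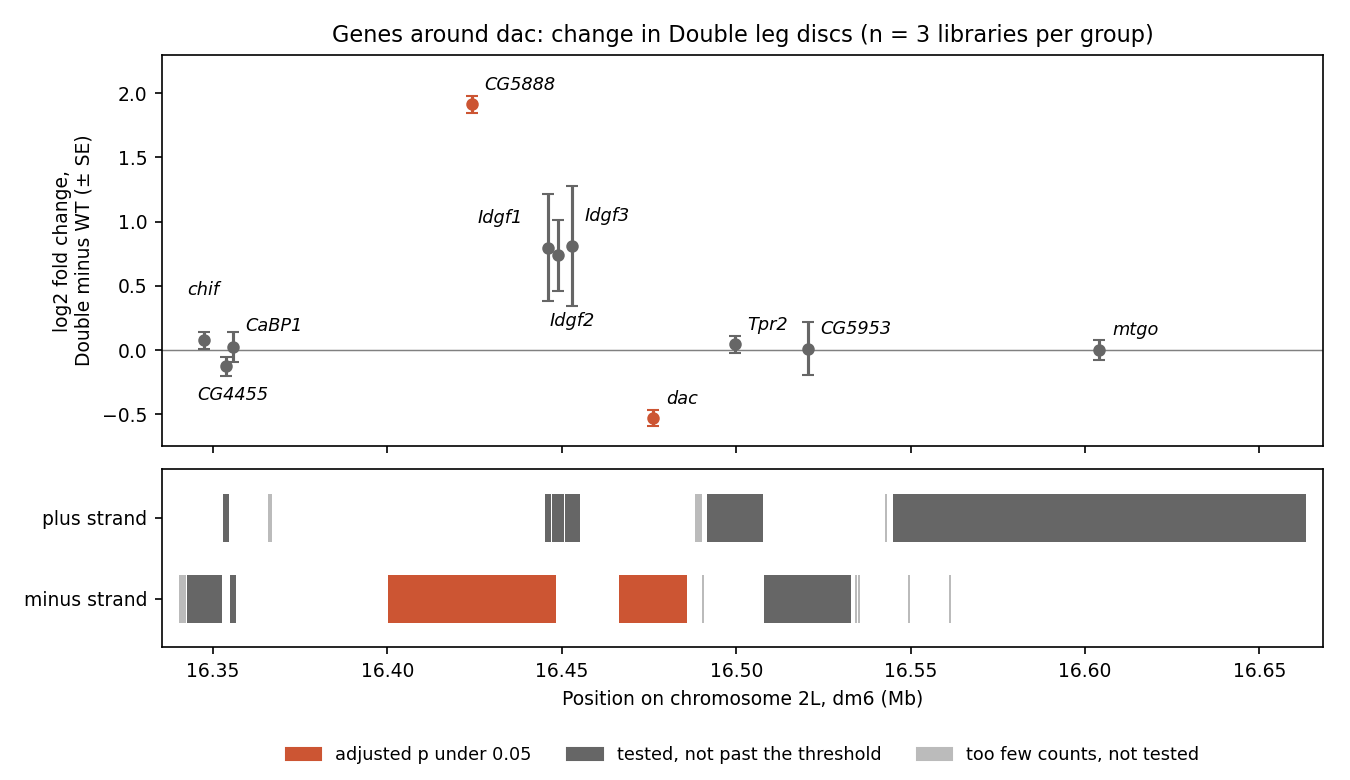
Upper panel, log2 fold change (Double minus WT, ± SE) of the 11 tested genes among dac and its neighbours, against the middle of each gene on chromosome arm 2L (dm6, Mb); lower panel, the annotated genes by strand, coloured by whether they passed the edgeR test. CG5888 at 1.91 and dac at -0.53 were the genes past the threshold.

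**Figure D2:**
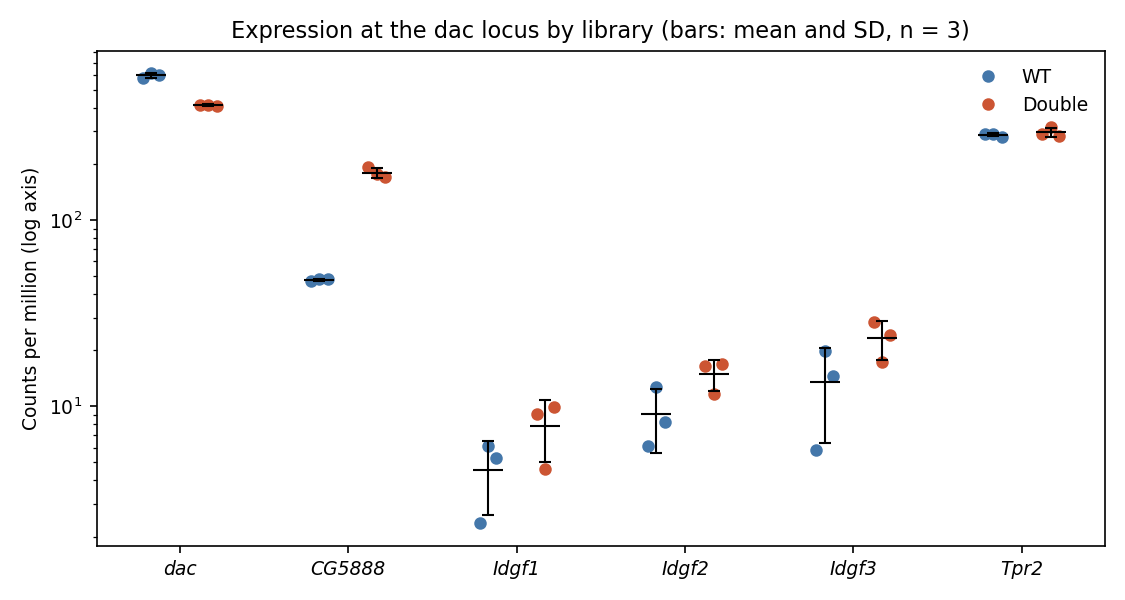
Expression of dac, CG5888, Idgf1, Idgf2, Idgf3 and Tpr2 in each library, in CPM on a log axis, with the mean and SD of each group (n = 3). The WT and Double libraries did not overlap for dac and CG5888, and they overlapped for Idgf1, Idgf2, Idgf3 and Tpr2.

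Across the transcriptome 131 of 8802 tested genes had changed, 48 higher and 83 lower in Double (edgeR, adjusted p under 0.05), and 27 of the higher and 47 of the lower genes differed at least 2-fold. The gene with the smallest adjusted p was CG10936, on 2R, which rose from 78.1 ± 5.57 to 633.1 ± 28.7 CPM (8.10-fold; edgeR adjusted p = 1.197e-06). miple1, which encodes a midkine and pleiotrophin family growth factor, fell from 71.8 ± 7.97 to 8.44 ± 0.58 CPM (log2 fold change -3.09; edgeR adjusted p = 5.209e-06; SD, n = 3 in each group). The counts of changed genes varied when single libraries were left out, which also lowers the power of the test. Leaving out WT replicate 1 gave 59 higher and 98 lower genes, WT replicate 2 gave 22 higher and 42 lower genes, WT replicate 3 gave 39 and 49, Double replicate 1 gave 24 and 43, Double replicate 2 gave 28 and 41, and Double replicate 3 gave 16 and 30.

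Among the 12 genes with the largest rises, 2 had no count in any WT library. Gr64a, which encodes a gustatory receptor for sugars, read 8.19 ± 1.01 CPM in Double and was at least 90.9-fold higher, and CG13032 read 5.67 ± 1.78 CPM and was at least 62.5-fold higher. These bounds take 3 counts over the WT group as the floor and cover counting error only. The ionotropic receptor pseudogene Ir51a rose by 4.27 on the log2 scale, Muc68Ca, a mucin gene, by 3.50, and Spn47C, a serpin gene, by 3.38. The rises were 2.96 for CG8665, 2.94 for Tmc, which encodes a transmembrane channel-like protein, 2.49 for Tg, a transglutaminase gene, 2.23 for CG13609 and 1.92 for the cuticle protein gene Cpr65Au. CG10936 and CG5888 complete the 12. Their edgeR adjusted p lay between 1.197e-06 for CG10936 and 0.04564 for Muc68Ca.

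Of the 12 largest falls, 2 ended at 0 counts in all 3 Double libraries. Cyp6a17, a cytochrome P450 gene on 2R, read 18.1 ± 4.05 CPM in WT and was at least 193-fold lower, and CG31259 read 4.70 ± 1.38 CPM in WT and was at least 50.3-fold lower, both against 3 counts over the Double group. CG5707 and Oseg2, which encodes an intraflagellar transport protein, are neighbours among the tested genes of 3L, with log2 fold changes of -4.67 and -4.50. The log2 fold changes were -4.63 for lncRNA:CR42646, -3.87 for Syt4, a synaptotagmin gene, -3.77 for asRNA:CR43767, -3.52 for the C-type lectin gene lectin-28C, -3.38 for Faa, which encodes fumarylacetoacetase, -3.15 for CG18343 and -2.91 for twit. asRNA:CR43767 is annotated as an antisense transcript, and its counts are uncertain for the reason given for CG5888. Of the 30 named genes past the threshold, 14 passed it in each of the 16 alternative settings run for single genes, among them CG5888, CG10936, miple1, Gr64a and Cyp6a17. Syt4 passed in 6, Muc68Ca and CG13609 in 7, CG8665 in 9, Cpr65Au and twit in 10, and Oseg2 and CG18343 in 11 of the 16. Without WT replicates 1, 2 and 3 in turn 26, 17 and 19 of the 30 passed, and without Double replicates 1, 2 and 3 in turn 19, 18 and 17 passed.

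**Figure D3:**
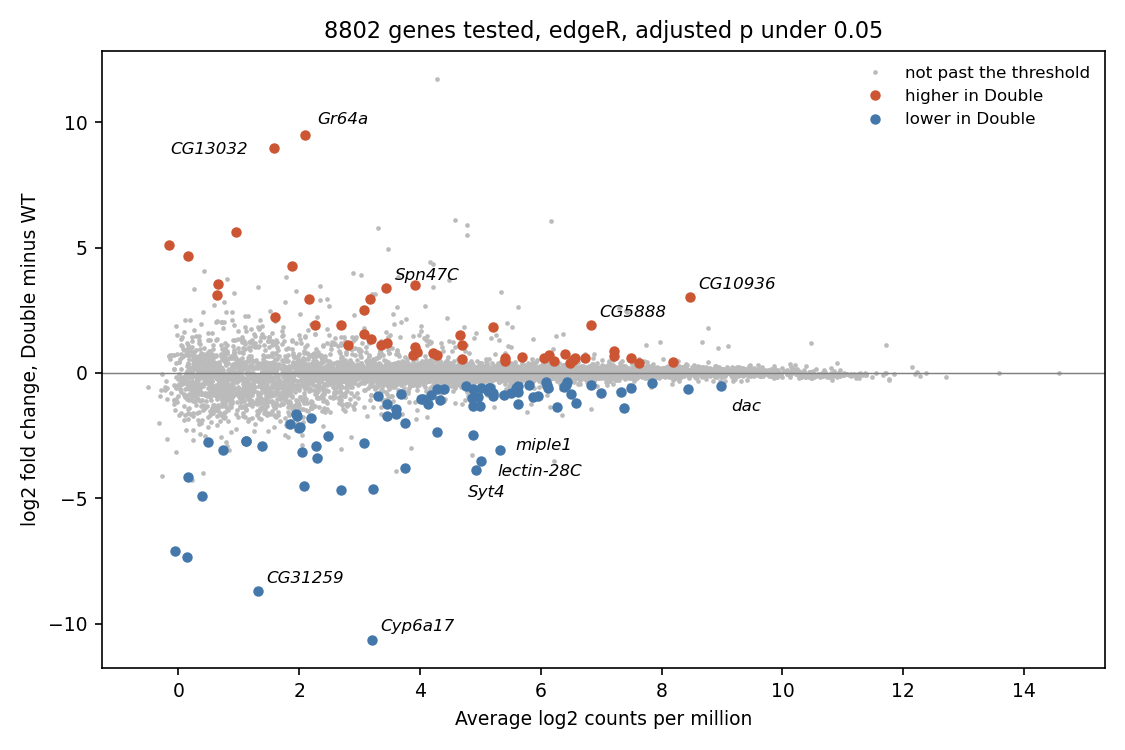
log2 fold change (Double minus WT) against average log2 CPM for the 8802 tested genes, each point a gene, with the 48 higher and 83 lower genes (edgeR, adjusted p under 0.05) in colour. The fitted values of genes at 0 counts in one group, such as Gr64a and Cyp6a17, depend on the prior count and are not bounds.

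The changed genes were spread over the chromosomes. Arm 2L held 34 changed genes of 1553 tested (2.19%), 2R held 26 of 1753 (1.48%), 3L held 33 of 1725 (1.91%), 3R held 23 of 2137 (1.08%) and X held 14 of 1496 (0.936%). Chromosome 4 held 1 of 86. The share on 2L had the smallest p of the 7 arms and chromosomes tested (two-sided Fisher's exact test, p = 0.01512; Benjamini-Hochberg adjusted p = 0.1058). Among the changed genes 9 pairs were direct neighbours among the tested genes, against a mean of 1.96 pairs in 10000 random draws of as many genes (permutation p = 4e-04). They were Axud1 with CG3609, CG10417 with lncRNA:CR42646, CG12964 with Pgant1, CG5707 with Oseg2, Gr64a with Gr64f, CG42673 with Tmc, CG4686 with Mrp5, CG32640 with CG32641 and CG34325 with CG32572. None of these pairs lay within 1 Mb of dac. The number of pairs was 2 without WT replicate 2 (permutation p = 0.0726) and 0 without Double replicate 3 (permutation p = 1). It was 4 without WT replicate 3, 4 without Double replicate 1 and 3 without Double replicate 2, each past the threshold. It was 28 with DESeq2 (permutation p = 1e-04, the smallest the draws can give), 2 with the salivary gland covariate (permutation p = 0.0407) and 46 with the neuron and glia covariate (permutation p = 0.0147).

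The patterning genes of the leg disc, other than dac, did not pass the test. Over all 8802 tested genes 1079 (12.3%) stood at an unadjusted p under 0.05. Of 24 tested genes of the proximo-distal axis 1 was lower, dac itself, also adjusted over the list alone, and the median log2 fold change of the list was 0.09. With dac included, 4 of the 24 stood at an unadjusted p under 0.05. After dac, rho had the smallest p, at 50.3 CPM in WT and 62.5 CPM in Double (edgeR adjusted p = 0.1429, or 0.05845 over the list alone). Dll, which specifies distal leg, read 332.0 CPM in WT and 391.9 CPM in Double (edgeR adjusted p = 0.2922). None of 21 genes of the antero-posterior and dorso-ventral axes, none of 24 genes of the Notch pathway and leg joints and none of 6 Hox genes passed, and the counts adjusted over the list alone were 0 in these 3 lists. At an unadjusted p under 0.05 stood 2, 3 and 2 members of these lists. Their members with the smallest p were mid and Mad, with log2 fold changes of 0.22 (SE 0.07) and 0.15 (SE 0.05), fng and E(spl)mgamma-HLH, with 0.18 (SE 0.06) and -0.49 (SE 0.16), and Scr and Antp, with -0.25 (SE 0.09) and 0.29 (SE 0.12). Of 81 tested developmental regulators that are Polycomb targets 1 was lower, again dac, and 15 stood at an unadjusted p under 0.05. The median of that list was 0.05 and its mean -0.10, opposite in sign, and the count adjusted over the list alone was 1 lower. None of 34 Polycomb and Trithorax group genes and none of 17 insulator and architectural protein genes passed, with 2 and 0 members at an unadjusted p under 0.05. None of 18 neural and sense organ precursor genes passed, with 2 at an unadjusted p under 0.05. Adjusted over the list alone the counts of these last 3 lists were 0.

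Over all 29 lists, 6 of 486 distinct tested members passed the edgeR test, and DESeq2 gave 24. Besides dac these were GstE1 and GstE8, glutathione S-transferase genes, Mp20 and up, and krimp. Of 14 tested genes of oxidative stress and xenobiotic detoxification, GstE1 fell by 2.17 on the log2 scale (SE 0.32; edgeR adjusted p = 0.01697) and GstE8 rose by 3.10 (SE 0.54; edgeR adjusted p = 0.03172), with 2 higher and 3 lower adjusted over the list alone. GstE1 passed in 11 of the 16 alternative settings (adjusted p up to 0.1036) and GstE8 in 7 of 16 (up to 0.1838). Without WT replicate 2, Double replicate 1, Double replicate 2 and Double replicate 3 in turn, the number of members past the threshold over all lists was 2, 2, 1 and 0. None passed among 30 genes of S phase and mitosis, 16 of apoptosis and JNK signalling, 21 of the ecdysone response, 17 of heat shock, 9 of antimicrobial immunity, 30 of oxidative phosphorylation and 40 cytoplasmic ribosomal protein genes. At an unadjusted p under 0.05 stood 4, 1, 2, 5, 1, 0 and 0 of these members in the same order, and none passed adjusted over the list alone. The ecdysone list had a median of -0.05 and a mean of 0.06 on the log2 scale, with 7 members above 0 and 14 below. Its members Hr3, Eip74EF and ftz-f1 were higher in Double without overlap of the groups. Their log2 fold changes were 1.29, 0.25 and 0.80 (edgeR adjusted p = 0.3034, 0.2113 and 0.4248). Whether the larvae of the 2 groups differed in stage was not tested.

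As whole lists, 9 were called by limma's camera with a preset correlation of 0.01, and none with an estimated correlation. The antero-posterior and dorso-ventral patterning list was shifted upward (median 0.10 on the log2 scale; camera adjusted p = 0.00821), and its adjusted p was 0.484 with an estimated correlation. The heat shock list was shifted upward (median 0.31, adjusted p = 0.00481), as were S phase and mitosis (median 0.10, adjusted p = 0.0198) and the Polycomb and Trithorax group (median 0.08, adjusted p = 0.0497). The cytoplasmic ribosomal protein list was shifted downward (median -0.08, adjusted p = 0.00539). The adjusted p of each of these 4 lists was 0.812 with an estimated correlation. The Polycomb and Trithorax call was also lost with RLE factors (camera adjusted p = 0.0566), with library totals (0.0737), with no count filter (0.0666) and with the stricter filter (0.0505). Its medians there were 0.0816, 0.0732, 0.074 and 0.0846, close to that of the main setting. Without WT replicate 1 its median was 0.02 (adjusted p = 0.742), and it was lost without Double replicate 2 (0.241) and Double replicate 3 (0.115). The summed expression of that list was 6734 CPM in WT replicate 1 and 8336 to 8634 CPM in the other 5 libraries. Without WT replicate 1 the S phase median was 0.04 (adjusted p = 0.497) and the ribosomal median -0.01 (adjusted p = 0.841). The S phase call was also lost without Double replicate 2 (median 0.04, adjusted p = 0.51) and the ribosomal call without Double replicate 1 (adjusted p = 0.0864). The S phase median was 0.17 without WT replicate 2 and 0.16 without Double replicate 1, the ribosomal median was -0.16 without WT replicate 3, and the heat shock median was 0.20 without WT replicate 2 and 0.64 without WT replicate 3, with these calls kept. With the fat body covariate the Polycomb and Trithorax, S phase and ribosomal calls were lost (camera adjusted p = 0.685, 0.199 and 0.794, medians 0.0264, 0.0721 and 0.0043). With the salivary gland covariate the Polycomb and Trithorax and ribosomal calls were lost (camera adjusted p = 0.237 and 0.831, medians 0.0544 and -8.53e-05). With the neuron and glia covariate the S phase and ribosomal medians were 0.17 and -0.13, with both calls kept. In the heat shock list Hsp68 read 20.3 ± 18.0 CPM in WT and 71.9 ± 13.9 CPM in Double (SD, n = 3 each), with an edgeR adjusted p of 0.472. By fry, which asks whether a list's genes move on balance one way, 2 lists passed, the antero-posterior and dorso-ventral list upward (adjusted p = 0.0171) and the muscle markers downward (adjusted p = 0.0486). By its mixed form, which asks for change in either direction, 12 of 28 lists passed, among them the Polycomb targets (adjusted p = 7.48e-05). The mixed form does not compare a list with the other genes. The Polycomb target list holds dac, its only member past the edgeR test. That list was called neither by camera (adjusted p = 0.735) nor by the one-way form of fry (adjusted p = 0.783).

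Markers of tissues that hand-dissected leg discs can carry differed widely between libraries. The summed expression of the fat body markers was 337.2, 7060 and 4968 CPM in WT replicates 1, 2 and 3 and 13820, 3459 and 8780 CPM in Double replicates 1, 2 and 3, a 41.0-fold range. The summed salivary gland markers read 487, 454 and 3974 CPM in WT and 3846, 1511 and 1992 CPM in Double in the same order, an 8.76-fold range. In WT replicates 1 and 2 most of that sum was CrebA (288.15 and 215.86 CPM) and sog (178.51 and 166.08 CPM). The glue gene Sgs3 alone ranged from 2.88 CPM in WT replicate 1 to 1167.26 CPM in Double replicate 1. The proximo-distal leg patterning genes had a range of 1.11-fold over the same 6 libraries. None of 10 fat body and none of 12 salivary gland markers passed the edgeR test, with 2 and 3 at an unadjusted p under 0.05. Adjusted over the list alone, 0 of the former and 2 of the latter were higher. WT replicate 1 stood apart from the other 5 libraries on the first principal component, at -61.0 against -4.81 to 25.9, a component that held 43.3% of the variance.

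Of 17 tested muscle markers 2 were lower in Double, Mp20, which fell from 6.36 ± 2.18 to 1.39 ± 0.46 CPM (edgeR adjusted p = 0.03837), and up, which encodes troponin T and fell from 5.50 ± 0.87 to 1.78 ± 0.18 CPM (edgeR adjusted p = 0.04372; SD, n = 3 in each group). Mp20 passed the test in 8 of the 16 alternative settings (edgeR adjusted p up to 0.1826) and up in 6 of 16 (up to 0.186). With single libraries left out, Mp20 passed only without WT replicate 1 and up in no case. Adjusted over the list alone 9 muscle markers were lower. The summed expression of the list, set by its most abundant members, read 1057, 2004 and 1844 CPM in WT and 1911, 1932 and 2015 CPM in Double. The list was called downward by camera (median -1.32, adjusted p = 0.000185), and its adjusted p was 0.484 with an estimated correlation. The muscle median was -0.71 without WT replicate 1 and -0.85 without WT replicate 2 and -0.63 with the fat body covariate, with the call kept. The eye-antennal disc markers were called downward by the same test (15 tested, median -0.74, adjusted p = 0.000185), the haemocyte markers downward (16 tested, median -0.36, adjusted p = 0.0264) and the salivary gland markers upward (median 0.38, adjusted p = 0.00154). The adjusted p of each of these 3 lists was 0.812 with an estimated correlation, and no eye-antennal or haemocyte marker passed the edgeR test, with 8 and 4 at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone. Whether dac and the eye-antennal markers moved together over the libraries was not tested. The haemocyte call was lost without WT replicate 2 (median -0.19, camera adjusted p = 0.312), Double replicate 1 (median -0.33, adjusted p = 0.0619) and Double replicate 2 (median -0.36, adjusted p = 0.199). It was also lost with the salivary gland (median -0.23, camera adjusted p = 0.0725) and neuron and glia covariates (median -0.19, adjusted p = 0.171). The salivary gland call was kept, but its median was 0.24, 0.02 and 5.15 without WT replicates 1, 2 and 3 in turn, and -0.03 and 0.63 without Double replicates 1 and 2. The same median was 3.32 with limma-voom, 2.67 with the replicate block, 0.10 with the fat body covariate and 3.81 with the neuron and glia covariate.

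The gut and Malpighian tubule list, with 2 tested members, was too small to be given a camera test. The remaining marker lists were tested and not called by camera. Of these, the neuron and glia markers had a median of -0.89 on the log2 scale, with 16 of 18 below 0 (camera adjusted p = 0.113). None passed the edgeR test among 14 adepithelial myoblast markers, 11 tracheal markers, 18 neuron and glia markers, 16 wing and haltere disc markers, 2 gut and Malpighian tubule markers, 13 cuticle genes and 8 genes of the list on the sex of the larvae, with 3, 3, 1, 3, 0, 4 and 4 members at an unadjusted p under 0.05 in the same order. Of 5 gonad and germline markers 1 was higher, krimp, a gene of the piRNA pathway, which rose from 1.96 ± 0.49 to 7.27 ± 1.32 CPM (edgeR adjusted p = 0.02623; SD, n = 3 in each group). krimp passed in 10 of the 16 alternative settings (adjusted p up to 0.1447). Adjusted over the list alone the counts were 2 higher and 1 lower for the gonad list, 2 and 2 for the sex list, 1 and 1 for the cuticle list, 0 higher and 1 lower for the tracheal list, and 0 for the myoblast, neuron and glia, wing and haltere, and gut lists. The median and mean of the log2 fold changes differed in sign for the adepithelial myoblast markers (0.03 and -0.01), the cuticle genes (-0.07 and 0.42) and the sex list (0.05 and -0.39). In the sex list 4 tested members were above 0 and 4 below. Its member lncRNA:roX1 read 230.93, 249.8 and 294.41 CPM in WT and 382.8, 344.5 and 347.22 CPM in Double. FDY read 40.41, 9.39 and 17.01 CPM in WT and 2.32, 1.45 and 0.6 CPM in Double. Whether the sex of the larvae differed between the groups was not tested.

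**Figure D4:**
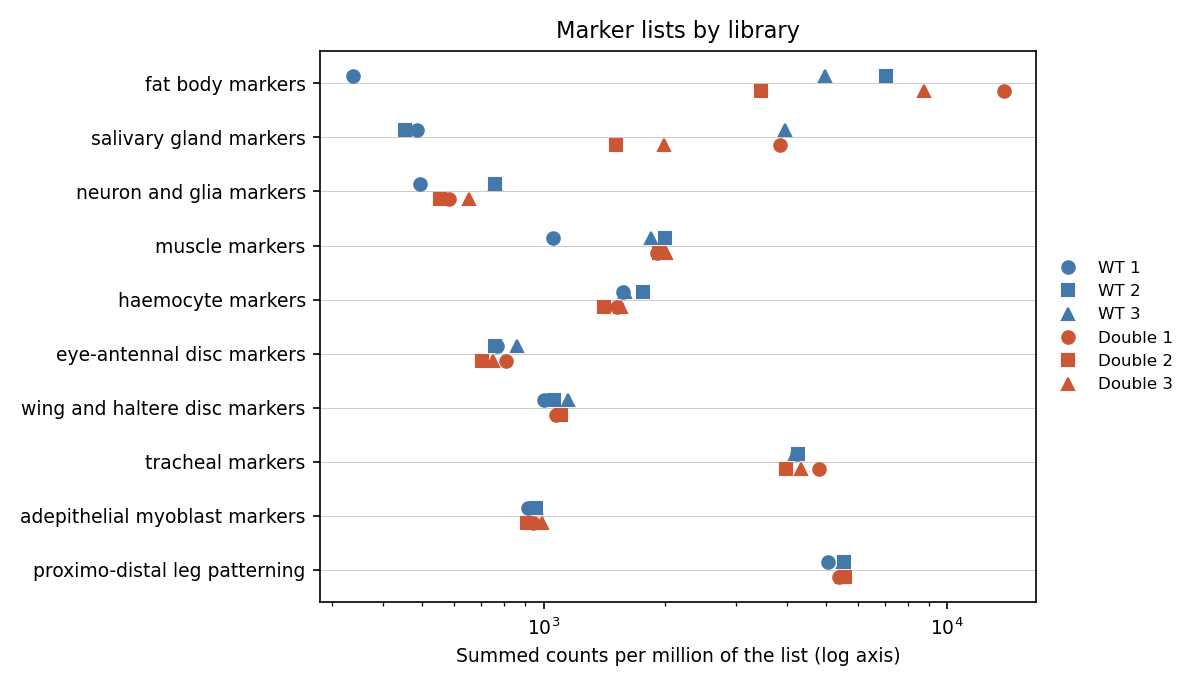
Summed CPM (log axis) of 10 gene lists in each library, coloured by group and shaped by replicate number. The fat body markers ranged 41.0-fold and the salivary gland markers 8.76-fold over the 6 libraries, and the proximo-distal leg patterning genes 1.11-fold.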

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

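The covariate settings were chosen after seeing the data. All other settings were planned. dac kept its direction in all 16 alternatives, at -0.55 to -0.51 with each library left out in turn, and lost its side of the threshold only without Double replicate 3 (log2 fold change -0.53, adjusted p 0.05363, range over the alternatives 1.14e-19 to 0.05363), and the cause was not tested. The test of the share of changed genes near dac stayed above the threshold in all settings, with 1 to 2 genes when libraries were left out, 3 with DESeq2, 3 in the 2000 kb window and 9 with the neuron and glia covariate (Fisher's exact test, p = 0.1189). The neighbour pairs lay between 0 and 10 with each library left out, and the test was lost without WT replicate 2 (2 pairs) and without Double replicate 3 (0 pairs). There were 28 pairs with DESeq2, 2 with the salivary gland covariate (permutation p = 0.0407), 46 with the neuron and glia covariate (permutation p = 0.0147), and 8 to 12 in the other settings that kept all 6 libraries. The p of 1e-04 with DESeq2, limma-voom and the fat body covariate is the smallest that the draws can give.

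The numbers of genes higher and lower were 48 and 83. They became 118 and 175 with DESeq2, which called all 131, 19 and 35 at an adjusted p under 0.01, 12 and 21 in the test against a 1.5-fold change, 19 and 34 with the salivary gland covariate and 306 and 237 with the neuron and glia covariate, which moved the share of higher genes from 36.6% to 56.4%. With each library left out they were 16 to 59 and 30 to 98, rising to 59 and 98 without WT replicate 1 and falling below 48 and 83 when any of the other 5 was left out. Apart from the stricter thresholds, the cause was not tested. Fewer libraries give the test less power, so a lower count need not mean that the changes rest on the library left out. limma-voom gave 39 and 65, and no other change of scaling or filter moved either count by over 1.5 times. The 6 list members past the threshold became 12 with no count filter, 24 with DESeq2, 13 with the replicate block, 10 with the fat body covariate, 2 with the salivary gland covariate and 43 with the neuron and glia covariate, and 0 to 8 with each library left out. The 9 lists called by camera became 0 with an estimated correlation and 2 with fry, and 7 to 10 with each library left out. The cytoplasmic ribosomal protein list reversed with the fat body covariate (median 0.0043), and the cause was not tested. Of the 30 named genes past the threshold none reversed in any alternative, and 15 to 30 passed it in the alternatives that kept all 6 libraries.

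The replicate numbers gave no clear pairing of the libraries. The correlations of same-numbered deviations were -0.0706, -0.251 and 0.389, and not every library correlated best with its own number. With 3 libraries per group these correlations cannot exclude a shared batch. With the replicate number as a block 67 genes were higher and 99 lower, 107 of the 131 were called, and the log2 fold change of dac was -0.53 (adjusted p 0.007156). Depth limits the genes near 1 CPM, where 1 count equals 0.0735 to 0.113 CPM.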

Other observations

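The tests on HIP, HIP-R, Cyp6a17 and Cyp6a23 and the correlations with fat body markers were chosen after the results were seen, and the covariates after the marker levels were seen. The tests on neighbour pairs and on the distance to dac were planned, but what they would show under each explanation was written after their results were seen. The following genes were among the 131 and were chosen after their values were seen, with no test of their families. spn-E, a gene of the piRNA pathway, fell from 12.6 to 6.74 CPM (edgeR adjusted p = 0.02798). The methuselah-like receptor gene mthl3 fell from 240.5 to 91.4 CPM (edgeR adjusted p = 1.425e-05), mthl8 had 0 counts in Double and was at least 20.4-fold lower, and mthl10 rose from 33.8 to 50.9 CPM (edgeR adjusted p = 0.006843). The serpin genes Spn38F and Spn28Dc fell by 0.64 and 0.59 on the log2 scale (edgeR adjusted p = 0.0367 and 0.03832). Ance, an angiotensin-converting enzyme homologue gene, fell from 424.0 to 269.0 CPM (edgeR adjusted p = 0.01465), and mre11, a DNA repair gene, from 81.0 to 43.3 CPM (edgeR adjusted p = 0.002233). The gene of the nucleosome remodelling subunit Acf rose from 113.6 to 181.4 CPM (edgeR adjusted p = 0.01697). Over the 16 alternative settings, mthl3 and mre11 passed the test in 16, mthl10 in 15, Acf in 12, Ance in 10, spn-E and mthl8 in 9, Spn38F in 7 and Spn28Dc in 6. Of the genes named next, HIP and HIP-R passed it in 16, and Cyp6a23 and Sgs1 in 4.

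For every 100 CPM of Fbp1, Fbp2 read 34.6, 5.48 and 7.13 CPM in the 3 WT libraries and 0.255, 0.321 and 0.251 CPM in the 3 Double libraries, although both are fat body genes. Fbp2 itself read 17.99, 190.52 and 204.45 CPM in WT and 19.2, 3.62 and 12.72 CPM in Double, so the groups overlapped. No fat body marker passed the edgeR test (smallest adjusted p = 0.3812), and the ratio was not tested. Sgs1, a salivary glue gene, read 0.44, 0.45 and 5.43 CPM in WT and 182.9, 129.9 and 109.2 CPM in Double (edgeR adjusted p = 0.06784). For every 100 CPM of Sgs3, another glue gene, it read 15.3, 2.26 and 0.958 CPM in WT and 15.7, 41.7 and 20.1 CPM in Double. Adh is listed at 0 in all 6 libraries.

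The real grouping gave 131 changed genes, and the highest of the other 9 of the 10 splits of the 6 libraries into 3 and 3 gave 0. With 10 splits the share cannot fall below 0.1, so they are too few for a share under 0.05. The other splits also mix WT and Double libraries in both groups, so a difference between WT and Double would itself lower their counts.

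Of the 131 changed genes 129 lay farther than 1 Mb from dac. This argues against a reach of under 1 Mb around dac, if the deletion lies there, as the whole cause. Strain variants linked along the chromosomes are a candidate explanation that predicts changed genes side by side, and 9 neighbour pairs were found against an upper limit of 5 in random draws (permutation p = 4e-04). That test is lost without WT replicate 2 or Double replicate 3, and neighbours that share regulation or reads, such as the paralogs CG32640 and CG32641, may give pairs too. An effect of lower dac or of the deletion on distant genes stays open and was not tested, since genotype and strain cannot be separated with these 2 groups.

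Idgf1, Idgf2 and Idgf3 read higher in Double and passed the test in 1 of 16 alternatives, the neuron and glia covariate, where their median log2 fold change was 1.21. Differing amounts of fat body may account for part of the difference: with the fat body covariate the median went from 0.796 to 0.294, just under the bound of 0.3 set beforehand, with Idgf1 at 0.268 (SE 0.292), Idgf2 at 0.41 (SE 0.204) and Idgf3 at 0.294 (SE 0.137), and without WT replicate 1 alone it was 0.476. Over the 6 libraries the log2 CPM of Idgf1, Idgf2 and Idgf3 had Pearson r of 0.948, 0.876 and 0.98 with that of the fat body markers (exact permutation p = 0.00278, 0.0139 and 0.00556, adjusted over 5 relations 0.0139, 0.0232 and 0.0139) and Spearman rho of 0.943, 0.886 and 0.943 (exact permutation p = 0.0167, 0.0333 and 0.0167, adjusted 0.0417, 0.0555 and 0.0417), so that Idgf2 missed the threshold by rho. The permutations ignored the group, so a difference between WT and Double in both measures would also raise these correlations. Without WT replicate 1 and Double replicate 1, the libraries farthest from the median, r was 0.903, 0.623 and 0.746, and -0.12 for CG5888 and 0.0842 for dac, which over all 6 libraries had r of 0.514 (exact permutation p = 0.301, adjusted 0.376; rho = 0.6, exact permutation p = 0.242, adjusted 0.302) and -0.428 (exact permutation p = 0.494, adjusted 0.494; rho = -0.2, exact permutation p = 0.714, adjusted 0.714). The covariates move the median in opposite directions, and an effect of the deletion on these neighbours of dac stays open. The neuron and glia sum is set mainly by nrv2 and CadN, so the result with that covariate may not reflect neural tissue.

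Some changed genes have near-identical copies. HIP fell from 163.0 to 92.9 CPM and HIP-R rose from 104.1 to 191.4 CPM, while their sum changed by 0.09 on the log2 scale, as reads moving between the copies would give, which is a candidate explanation for both. Cyp6a17 had 0 counts in Double, and its adjacent paralog Cyp6a23 had a log2 fold change of -2.92 (SE 0.66, edgeR adjusted p = 0.08878), lower rather than higher, which argues against reads moving to that copy. A strain variant that removes Cyp6a17 stays open and was not tested, and no biological explanation was tested for either pair.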
